A study of Mus musculus with 62 samples.

How the data were processed

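RNA of mouse brown adipose tissue was measured in 62 libraries of 12 groups: CAC (cachectic melanoma cells), NCAC (non-cachectic melanoma cells) and Con (mock injection), each at 2, 4, 6 and 8 weeks. Per the labels, RNA was extracted with Trizol, stranded mRNA libraries were prepared with a TruSeq kit and sequenced on an Illumina NovaSeq instrument, and the values refer to mm10. The deposited file holds TPM, a transcript abundance scaled for length and library size, for 47643 gene symbols, and the authors give no aligner, annotation or software version. Every column summed to the same fixed total when checked, as TPM should, and all columns could be assigned to a group from the sample titles. TPM keeps no read counts, so the depth per library is unknown and no counting interval could be computed. The extraction text mentions another tumour model at another time, the series text and the sample labels name different mouse strains, and 1 sample number occurs in 2 titles at 4 weeks; the groups follow the sample labels.

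Values were taken as log2(TPM + 1), a scale that understates changes of genes with low values, and genes with at least 1 TPM in at least 5 libraries were kept, which left 12581. Group means were fitted to all 62 libraries in 1 model with limma 3.58.1 (trended empirical Bayes, R 4.3.3), and 16 contrasts were tested: CAC against Con, CAC against NCAC and NCAC against Con at each week, the change of the CAC against Con difference from 2 to 6, 2 to 8 and 6 to 8 weeks, and Con at 8 against 2 weeks. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast. Genes called against both Con and NCAC at 8 weeks were counted against the number expected from the list sizes, and after dividing the CAC libraries so that none was shared. In 50 simulations with unchanged groups at most 0 genes were called in both, but each gene was drawn independently there. Those simulations therefore cannot show the overlap that arises when the genes of a library vary together. On data simulated for CAC against Con with changes added, 95.5% of genes with a true log2 change of 1 were recovered at 8 weeks and 89.6% at 4 weeks. The changes were placed only in genes above a minimum mean level, and the noise was drawn independently for each gene.

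The comparisons, tests, 35 gene lists (22 of processes and 13 of cell types, 552 genes of which 470 were tested), the rule for named genes and 9 kinds of alternative were fixed before the data were examined. Lists were tested with camera of limma at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over the 280 list tests of the CAC contrasts. Beside counts over all genes, members were also counted with p adjusted over the list alone. Genes were named by rule: the 10 highest and 10 lowest log2 changes for CAC against Con at 8 weeks, the 5 highest and 5 lowest for the other contrasts of CAC, and the 3 highest and 3 lowest for NCAC against Con and for the change from 2 to 8 weeks, among called genes with a mean of at least 5 TPM in the higher group and without predicted genes; a few members of each list; and Ucp1, Dio2, Adrb3, Ppargc1a, Lep, Adipoq, Pnpla2, Fasn, Fkbp5 and Lcn2. Of the list members chosen in this way 1 gene is not reported here. Adipoq and Lcn2 rose at 8 weeks against Con, by 0.61 (SE 0.12) and 2.21 (SE 0.72). Library measures (the percent of TPM from mitochondrially encoded genes and the mean log2 value of the skeletal muscle list) were compared with exact permutation tests, 2-sided, adjusted over 12 contrasts each.

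The alternatives fixed in advance were a pseudocount of 0.1, no filter (23425 genes), a filter at 5 TPM (8727 genes), median-of-ratios rescaling, quantile normalization, a fit of only the groups compared, library weights, the replicate number of the labels as a block, and leaving out each library in turn. Added after the data were seen were removal of mitochondrially encoded genes with rescaling of the rest, the mean of the skeletal muscle list as a covariate, that covariate together with median-of-ratios rescaling, and the fit without Con libraries 3 and 4 of 4 weeks. For each count, 100 splits of the same libraries, the real split included, were refitted. Gene positions are from the GENCODE annotation for mm10, matched by symbol. In a separate reference of gene names 45134 of the 47643 symbols were found. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. No library was left out of the reported values.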

Results

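The series measured RNA in brown adipose tissue, the fat that burns fuel to make heat, from mice followed for 8 weeks. The mice had received melanoma cells described as cachectic (CAC), melanoma cells described as non-cachectic (NCAC) or a mock injection (Con). Cachexia is the loss of fat and muscle that accompanies some tumours. Tissue was taken 2, 4, 6 and 8 weeks after injection, which makes 12 groups and 62 libraries, with 5 biological replicates per group except CAC at 8 weeks, which had 7. The deposited values are TPM, a transcript abundance scaled for length and library size, for 47643 gene symbols. TPM keeps no read totals, so the depth of each library is unknown, and no interval or detection floor can be given. Between 10851 and 12347 genes reached at least 1 TPM in a library. The sample labels name C57BL/6J mice while the series text names nude mice. The same sample number stands in the titles of 1 CAC and 1 Con library at 4 weeks. The strain and those labels remain open. Coordinates are from mm10.

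Transcripts encoded by the mitochondrial genome took most of the fixed TPM total, and their share was lower in CAC late in the course. At 8 weeks the share was 50.8% ± 3.67 (SD, n = 7) in CAC, 59.8% ± 2.33 (n = 5) in NCAC and 62.8% ± 2.33 (n = 5) in Con. Exact permutation tests, 2-sided, over 792 splits gave p = 0.00126 for CAC against Con and p = 0.00253 for CAC against NCAC, adjusted over 12 tests to 0.0151 and 0.0152. At 6 weeks it was 52.3% ± 1.12 in CAC and 61.1% ± 3.80 in Con (n = 5 each, exact p = 0.00794, adjusted p = 0.0318), with 56.8% ± 5.43 in NCAC (exact p = 0.143 against CAC). At 2 weeks it was 56.2% ± 1.31 in CAC, 58.2% ± 1.17 in Con and 58.5% ± 1.78 in NCAC. Exact permutation p was 0.0397 against Con and 0.0317 against NCAC (adjusted p = 0.0953 and 0.0951). At 4 weeks it was 55.9% ± 1.37 in CAC, 50.7% ± 10.1 in Con and 57.2% ± 1.70 in NCAC (exact p = 0.437 and 0.214). Con libraries 3 and 4 at 4 weeks held 39.6% and 39.7%, against 57.1% to 58.7% in the other 3. A lower share of these transcripts leaves more of the total to all other genes. The median log2 difference over all 12581 tested genes between CAC and Con was 0.09 at 2 weeks, -0.08 at 4 weeks, 0.18 at 6 weeks and 0.28 at 8 weeks. Directions are therefore also given after median-of-ratios rescaling, which takes this shift out.

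**Figure D1:**
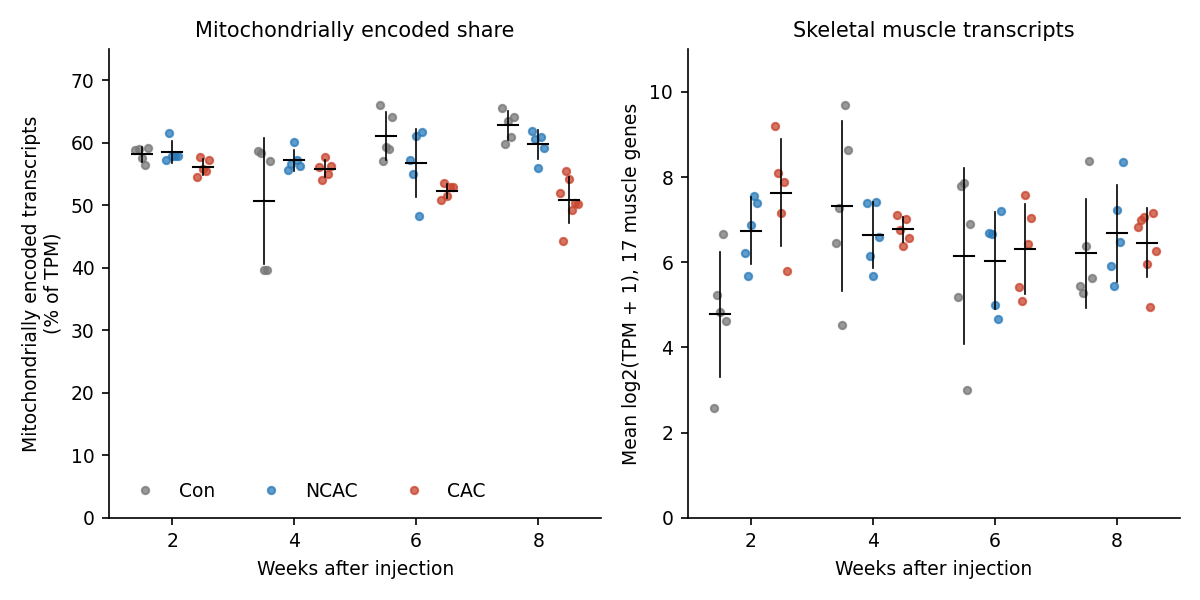
Each point is 1 library, ordered by week after injection and by arm; the left axis gives the percent of TPM from mitochondrially encoded genes and the right axis the mean log2(TPM + 1) of 17 skeletal muscle genes. Horizontal lines are group means and vertical lines 1 SD. At 8 weeks the mean mitochondrial share was 50.8% in CAC and 62.8% in Con, and at 2 weeks the muscle mean was 7.63 in CAC and 4.78 in Con.

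CAC was compared with Con at 8 weeks to ask how brown fat differs after the longest growth of the cachectic tumour. Genes of secreted defence proteins were among the 10 largest rises. Itih4, an acute phase protein (chromosome 14, 30886476 to 30902353), stood at 863 ± 397 TPM (SD, n = 7) in CAC and 1.33 ± 0.250 TPM (n = 5) in Con, a log2 change of 8.09 (SE 0.62, adjusted p = 1.01e-14). The complement component C4b (chromosome 17, 34728380 to 34743882) rose by 5.26 (SE 0.34, adjusted p = 3.98e-17), from 14.05 ± 3.96 to 609 ± 212 TPM. The chemokine Cxcl13 (chromosome 5, 95956951 to 95961068) rose by 5.29 (SE 0.60) and Ccl8 (chromosome 11, 82115185 to 82116799) by 4.14 (SE 0.46). For these 4 genes all 7 CAC libraries lay above every Con library. The remaining members of the 10 largest rises were the protease inhibitors Serpina3n (5.23, SE 0.48) and Serpina3k (3.96, SE 0.55), haptoglobin Hp (4.66, SE 0.48), the drug-metabolising Cyp2b10 (4.63, SE 0.96), the metal-binding Mt2 (4.30, SE 0.48) and the glucocorticoid-induced co-chaperone Fkbp5 (4.21, SE 0.66). Library 3 of CAC stood apart from the other 6, with 41.9 TPM of Itih4 where the others held 709 to 1176 TPM. C4b with C4a, Mt2 with Mt1 and the Serpina3 genes are close paralogs, so values of single members are uncertain.

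Signalling through IL-6 and STAT3 drives the acute phase response, and of the 21 tested genes of that list 19 rose at 8 weeks and 0 fell, with the same counts after rescaling. Serpina3n reached 508 ± 306 TPM (SD, n = 7) against 9.49 ± 3.16 TPM (n = 5), Hp 5951 ± 3825 against 172 ± 38.2 TPM, and the plasma glycoprotein gene Lrg1 326 ± 190.1 against 23.6 ± 6.49 TPM. Camera, which tests a list against all other genes, gave an adjusted p = 1.11e-10 with its preset correlation and an adjusted p = 0.344 with an estimated correlation. Adjusted over the list alone, 19 rose. Macrophage markers also rose: 11 of 13 were higher and 0 lower (10 and 0 after rescaling; 12 adjusted over the list alone), among them the scavenger receptor Cd163, at 21.5 ± 8.10 against 2.60 ± 0.344 TPM, and the complement subunit C1qa (log2 change 1.67, SE 0.24). The macrophage list gave an adjusted p = 0.00039 and an adjusted p = 0.598 with an estimated correlation. Of 7 neutrophil markers 5 rose on either scale and 0 fell, including S100a8 (1.15) and S100a9 (1.34). Adjusted over the list alone, 5 rose. On TPM the list as a whole did not pass the camera test (adjusted p = 0.407, and adjusted p = 0.773 with an estimated correlation). Its median was 1.15, against 0.28 over all genes. After rescaling its camera test at the preset correlation pointed up (adjusted p = 0.027).

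Genes of protein folding, proteolysis and glucocorticoid response were also counted at 8 weeks, where 6549 of all 12581 tested genes were higher on TPM. In the unfolded protein response list 13 of 14 rose (7 after rescaling, 14 adjusted over the list alone; adjusted p = 0.00464, and adjusted p = 0.605 with an estimated correlation), with the transcription factor Xbp1 up by 1.17 (SE 0.21) and the disulfide isomerase Pdia4 up by 0.89 (SE 0.14). In the list of ubiquitin ligases, autophagy and FOXO targets 15 of 20 rose (7 after rescaling, 17 adjusted over the list alone; adjusted p = 0.0129, and adjusted p = 0.675 with an estimated correlation). Its members include the autophagosome gene Map1lc3b (1.10, SE 0.12), the protease Ctsl (1.26, SE 0.16) and Atg7 (0.86, SE 0.12). Without CAC library 1 the adjusted p of this list was 0.0612. Of 17 glucocorticoid-responsive genes 13 rose and 1, the imprinted growth inhibitor Cdkn1c (-1.41, SE 0.21), fell, while after rescaling 8 rose and 2 fell. Fkbp5 reached 84.01 ± 48.3 TPM (SD, n = 7) against 2.85 ± 2.15 TPM (n = 5), and Mt1 rose by 3.24 (SE 0.38). On TPM that list did not pass the camera test (adjusted p = 0.313, and adjusted p = 0.794 with an estimated correlation). Its median was 1.15, against 0.28 over all genes. Adjusted over the list alone, 13 rose and 1 fell. After rescaling its camera test at the preset correlation pointed up (adjusted p = 0.00507). Of 14 integrated stress response genes 12 rose, or 5 after rescaling, and 12 adjusted over the list alone. On TPM the list had an adjusted p = 0.363, and an adjusted p = 0.781 with an estimated correlation. After rescaling its camera test at the preset correlation pointed up (adjusted p = 0.0356).

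The uncoupling gene and transcripts of the mitochondrial genome were lower in CAC at 8 weeks. Ucp1, the uncoupling protein that makes brown fat produce heat (chromosome 8, 83290352 to 83298452), fell by 0.82 on the log2 scale (SE 0.25, adjusted p = 0.00571), with 3061 ± 1209 TPM (SD, n = 7) in CAC and 5062 ± 532 TPM (n = 5) in Con. Letmd1 changed by -0.46 (SE 0.13). In the list of thermogenesis and brown adipocyte identity, 3 of 22 genes rose and 4 fell, against 0 and 8 after rescaling. Its median was 0.04, -0.24 relative to all genes, its mean was -0.04 and its test pointed down (adjusted p = 7.46e-06; adjusted p = 0.373 with an estimated correlation; 1 rose and 2 fell adjusted over the list alone). The beta-3 adrenergic receptor Adrb3 changed by -0.86 (adjusted p = 0.0253), a call that ended without CAC library 1, 4 or 6 or Con library 1 or 2, at adjusted p = 0.0544 to 0.0972. Dio2 (0.59, adjusted p = 0.417) and Ppargc1a (0.07, adjusted p = 0.903), both linked to cold response, did not pass the test. Of 13 respiratory genes of the mitochondrial genome 9 fell and 0 rose (12 and 0 after rescaling; 10 fell adjusted over the list alone), such as mt-Nd2 (-0.52, SE 0.11) and mt-Cytb (-0.29, SE 0.06), the latter at 0.12 under quantile normalization. This list had an adjusted p = 1.62e-16, and an adjusted p = 0.093 with an estimated correlation.

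The direction of several fuel pathways at 8 weeks depended on the scale. Of 30 nuclear respiratory chain genes 8 rose and 0 fell on TPM, and 0 rose and 16 fell after rescaling. On TPM that list did not pass (adjusted p = 0.173, and adjusted p = 0.82 with an estimated correlation), while 8 rose adjusted over the list alone. Its median was 0.12, its mean 0.14 and its test pointed down. After rescaling the camera test at the preset correlation also pointed down (adjusted p = 3.07e-06). Of 16 genes of the tricarboxylic acid cycle 4 rose and 3 fell, against 1 and 11 after rescaling (adjusted p = 0.00886; adjusted p = 0.675 with an estimated correlation; 4 rose and 3 fell adjusted over the list alone), with Suclg1 lower on either scale (-0.39, SE 0.08). Of 21 fatty acid oxidation genes 2 rose and 2 fell, against 1 and 12 after rescaling (adjusted p = 0.000163; adjusted p = 0.572 with an estimated correlation; 1 rose and 0 fell adjusted over the list alone). The last 2 lists had a positive median and mean and a test that pointed down. Some single lipolysis genes rose. Pnpla2, the lipase that starts triglyceride breakdown, went from 1019 ± 84.9 TPM (SD, n = 5) to 1857 ± 332 TPM (n = 7), a log2 change of 0.85 (SE 0.12) and 0.49 after rescaling. Its co-activator Abhd5 (0.95, SE 0.18) and the fatty acid carrier Fabp4 (0.73, SE 0.13) also rose. In the whole lipolysis list 7 of 16 rose and 1 fell, or 5 and 4 after rescaling (adjusted p = 0.639; adjusted p = 0.867 with an estimated correlation; 7 rose and 1 fell adjusted over the list alone). The fatty acid desaturase Scd1 rose by 1.10 (SE 0.26), while Fasn (0.07, adjusted p = 0.778) and the satiety hormone gene Lep (-0.84, adjusted p = 0.139) did not pass the test. The adipokine adipsin, Cfd, rose by 1.79 (SE 0.31) and the angiotensin precursor Agt by 2.85 (SE 0.40).

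Transcripts of gland and surface epithelium were among the largest falls at 8 weeks. The water channel Aqp5 fell by 2.44 (SE 0.70, adjusted p = 0.00324), with 0.515 ± 0.590 TPM (SD, n = 7) in CAC and 8.32 ± 5.71 TPM (n = 5) in Con, and the keratins Krt19 and Krt8 by 2.42 (SE 0.73) and 2.30 (SE 0.79), although reads of keratin genes and their pseudogenes can be hard to assign. Of 13 genes in the list of mammary and skin epithelium 5 fell and 0 rose, also after rescaling (adjusted p = 3.1e-09; adjusted p = 0.405 with an estimated correlation; 4 fell adjusted over the list alone). Krt18 (-2.22, SE 0.87) lost its call without CAC library 2, 4 or 7 or Con library 3 or 5, at adjusted p = 0.0503 to 0.082. The growth factor gene Ptn (-1.76, SE 0.71) lost it without CAC library 2, 4 or 7 or Con library 3, 4 or 5 (0.0599 to 0.101), and Ly6d (-1.70, SE 0.70) without CAC library 2, 4 or 7 or Con library 2, 4 or 5 (0.0636 to 0.085). Epcam (-1.63, SE 0.70) lost it without CAC library 1, 2, 3, 4 or 7 or Con library 2, 3, 4 or 5 (0.0504 to 0.121). The rest of the 10 largest falls held: the myokine precursor Fndc5 (-1.56, SE 0.30), the vascular peptide Apln (-1.54, SE 0.29) and Mmd2 (-1.45, SE 0.43). Among other cell types, limma called 0 of 17 skeletal muscle genes, with 0 higher and 0 lower at an unadjusted p under 0.05 and 0 adjusted over the list alone. The median and mean of that list were positive and its test pointed down (adjusted p = 0.00187, and adjusted p = 0.714 with an estimated correlation). Without Con library 4 the adjusted p was 0.0556. After rescaling the camera test at the preset correlation did not pass (adjusted p = 0.838). The immunoglobulin gene Ighm fell by 1.45 (SE 0.37), and the capillary gene Plvap rose by 2.04 (SE 0.25).

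In all, 6797 of 12581 genes differed between CAC and Con at 8 weeks by limma, 6549 higher and 248 lower in CAC, and 7471 had an unadjusted p under 0.05. After median-of-ratios rescaling 3333 differed, 1680 higher and 1653 lower. That rescaling brings the median over all genes to about 0 (-0.01), which by itself evens the balance of calls. Leaving out any 1 library gave between 5596 and 7323 genes. Of the 35 lists 15 passed with the preset correlation, 4 up and 11 down, and 0 with an estimated correlation, here and in each other comparison of CAC.

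**Figure D2:**
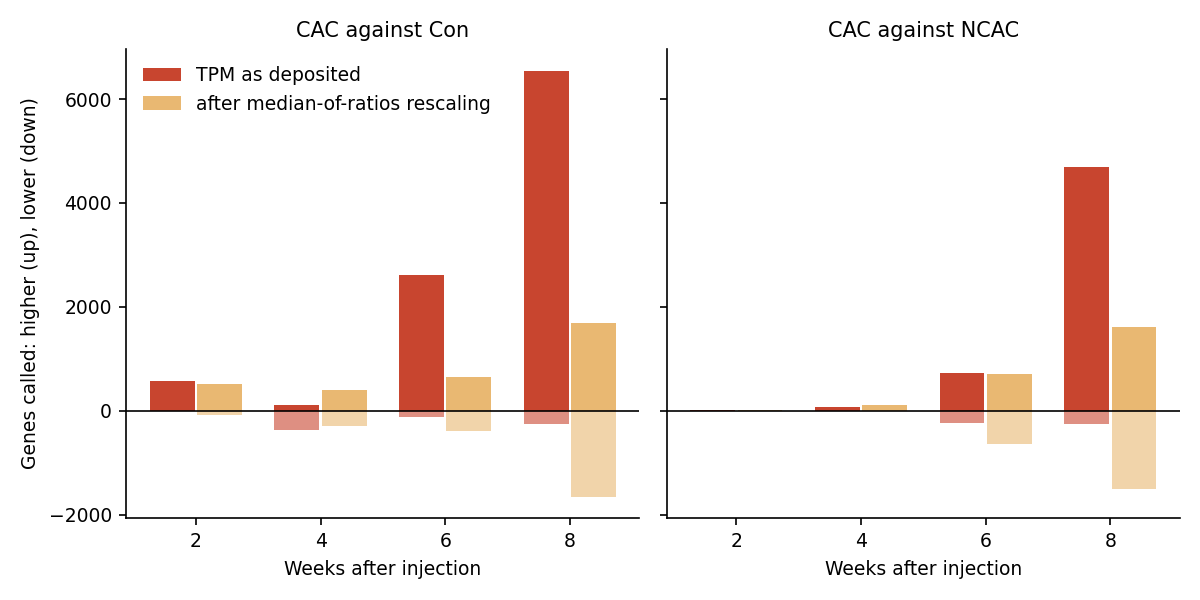
Bars give the number of genes past an adjusted p of 0.05 at each week, upward for genes higher in CAC and downward for genes lower in CAC, on TPM as deposited and after median-of-ratios rescaling. For CAC against Con at 8 weeks the split was 6549 higher and 248 lower on TPM, and 1680 higher and 1653 lower after rescaling.

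CAC was also set against NCAC at 8 weeks, where both arms had received melanoma cells. Cachexia cannot be told apart here from other differences between the 2 kinds of cells or their tumours. Itih4 again rose most, by 8.07 (SE 0.62) over 1.42 ± 0.701 TPM (SD, n = 5) in NCAC, then C4b by 5.37 (SE 0.34), Cxcl13 by 4.81 (SE 0.60) and Serpina3n by 4.62 (SE 0.48), followed by Hp at 4.40 (SE 0.48). In the IL-6 and STAT3 list 18 of 21 rose on either scale (18 adjusted over the list alone; adjusted p = 2.69e-13, and adjusted p = 0.237 with an estimated correlation). Of 13 macrophage markers 12 rose, or 11 after rescaling (12 adjusted over the list alone; adjusted p = 2.1e-07, and adjusted p = 0.433 with an estimated correlation). The unfolded protein response had 11 of 14 higher (6 after rescaling, 13 adjusted over the list alone; adjusted p = 0.00507, and adjusted p = 0.605 with an estimated correlation). Of the mitochondrial genome list 7 of 13 fell (9 after rescaling, 8 adjusted over the list alone; adjusted p = 5.45e-11, and adjusted p = 0.226 with an estimated correlation). Apln fell by 1.91 (SE 0.29), and Ucp1 stood at 6263 ± 2693 TPM in NCAC (log2 difference -1.03, adjusted p = 0.00124). Of 13 epithelial genes 5 fell on either scale (5 adjusted over the list alone; adjusted p = 4.5e-09, and adjusted p = 0.405 with an estimated correlation). Their calls were fragile: Krt18 (-2.31) was lost without CAC library 2, 4 or 7 or NCAC library 3, 4 or 5 (adjusted p = 0.0572 to 0.0723). So were Krt8 (-2.20) without NCAC library 4 or 5 (0.0548 to 0.0715), Krt19 (-2.15) without NCAC library 4 (0.0566) and Epcam (-2.04) without NCAC library 5 (0.0685).

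Between CAC and NCAC at 8 weeks 4947 genes differed, 4698 higher and 249 lower, and 3105 after rescaling, 1604 higher and 1501 lower. With only the compared groups in the fit 2736 differed. Against both Con and NCAC 4608 genes passed in the same direction, 4455 higher and 153 lower, where the sizes of the lists alone would give 2445.5 and 4.91. The comparisons share the CAC libraries. With those libraries divided into sets of 4 and 3, no CAC library was shared between the comparisons. The median overlap over 20 divisions was then 2611 (1042 to 3293), where 1400.4 would be expected from the list sizes. That expected number takes the lists as independent. They need not be, because the variance of each gene was estimated over libraries of all groups. The median log2 difference over all genes was also positive in both comparisons, 0.28 against Con and 0.21 against NCAC. The excess is therefore not free of sharing. After rescaling 2342 genes passed in both, 1234 higher and 1108 lower.

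**Figure D3:**
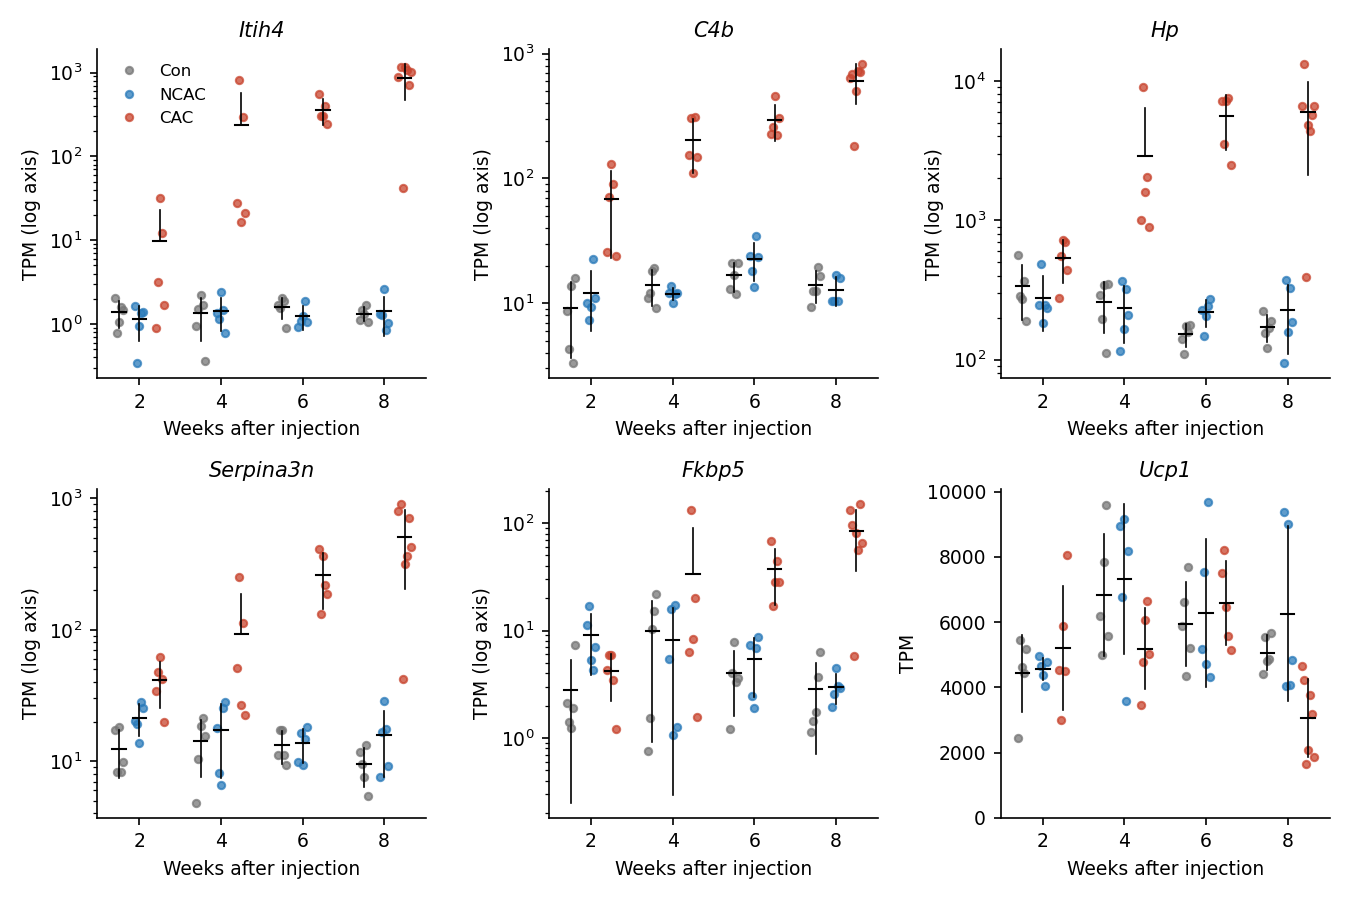
TPM of 6 genes in each library by week after injection and arm, on a log axis except for Ucp1. Horizontal lines are group means and vertical lines 1 SD, with the lower arm left out where it would reach 0 on a log axis. At 8 weeks Itih4 averaged 863 TPM in CAC against 1.33 TPM in Con, and Ucp1 3061 against 5062 TPM, a fall that also held after rescaling.

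At 6 weeks the acute phase genes were already raised in CAC, against either comparison group. Itih4 reached 362 ± 125 TPM (SD, n = 5) against 1.61 ± 0.449 TPM in Con (n = 5), a log2 change of 7.08 (SE 0.67), and Hp 5580.3 ± 2374 against 153 ± 28.2 TPM (5.07, SE 0.52). Cxcl13 rose by 4.44 (SE 0.64), Serpina3n by 4.13 (SE 0.52) and C4b by 4.04 (SE 0.37). In the IL-6 and STAT3 list 15 of 21 rose (14 after rescaling, 17 adjusted over the list alone; adjusted p = 1.03e-13, and adjusted p = 0.226 with an estimated correlation). So did 7 of 13 macrophage markers (6 after rescaling, 7 adjusted over the list alone; adjusted p = 0.00462, and adjusted p = 0.675 with an estimated correlation). Of 13 mitochondrial genome genes 4 fell on either scale (6 adjusted over the list alone; adjusted p = 1.64e-10, and adjusted p = 0.226 with an estimated correlation). Among the 5 largest falls, 3 kept their calls without any 1 library: the macrophage product Retnla (-1.65, SE 0.46), the carbonic anhydrase Car14 (-1.48, SE 0.29) and the retinol carrier Rbp4 (-1.43, SE 0.27). Mmd2 (-1.46) lost its call without CAC library 3 or Con library 5 (adjusted p = 0.0515 to 0.0674) and the antigen-presenting H2-Aa (-1.30) without CAC library 1 or Con library 5 (0.0727 to 0.124). In all 2731 genes differed by limma, 2608 higher and 123 lower, and 1050 after rescaling, 652 higher and 398 lower. The count was 1807 without CAC library 4, 1593 without Con library 1 and 1601 without Con library 5.

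Against NCAC at 6 weeks 977 genes differed, 732 higher and 245 lower, and 1342 after rescaling, 704 higher and 638 lower, with 2442 under library weights. The count was 593 without CAC library 1. Itih4 (7.29, SE 0.67), Cxcl13 (5.06, SE 0.64) and Hp (4.56, SE 0.52) rose most, with Serpina3n at 4.08 and C4b at 3.65. The IL-6 and STAT3 list had 14 of 21 higher on either scale (15 adjusted over the list alone; adjusted p = 6.07e-17, and adjusted p = 0.226 with an estimated correlation). Of 13 macrophage markers 6 rose on either scale (8 adjusted over the list alone; adjusted p = 0.000298, and adjusted p = 0.597 with an estimated correlation). Of 22 extracellular matrix genes 2 rose and 4 fell, or 2 and 10 after rescaling (3 rose and 13 fell adjusted over the list alone; adjusted p = 1.21e-05, and adjusted p = 0.569 with an estimated correlation). Mmd2 fell by 2.81 (SE 0.46), Rnase2a by 2.23 (SE 0.50) and Retnla by 2.17 (SE 0.46), all 5 CAC libraries lying below every NCAC library. The size of the last 2 rested on NCAC library 4, with 105.3 TPM of Rnase2a and 1284 TPM of Retnla where the other 4 held at most 2.56 and 131 TPM. Without it Rnase2a was -1.20 (adjusted p = 0.0123) and Retnla -1.42 (adjusted p = 0.0119). With only the compared groups in the fit neither was called (adjusted p = 0.163 and 0.0837). The growth factor Areg (-2.36) lost its call without NCAC library 1 (adjusted p = 0.0753), and Aqp5 (-2.30) without any 1 of the 5 CAC libraries or NCAC library 1, 2 or 5 (0.0625 to 0.19).

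At 4 weeks a smaller set of the same genes stood out in CAC. Itih4 averaged 235 ± 344 TPM (SD, n = 5) against 1.34 ± 0.716 TPM in Con (log2 change 5.10, SE 0.67) and 1.43 ± 0.601 TPM in NCAC (5.02, SE 0.67). C4b averaged 205 ± 94.3 TPM, a rise of 3.72 (SE 0.37) over Con and 3.87 (SE 0.37) over NCAC, and its paralog C4a rose by 2.31 and 2.53. Ccl8 rose by 3.02 (SE 0.50) and 2.75 (SE 0.50), and Hp by 3.01 (SE 0.52) and 3.14 (SE 0.52). For these 5 genes all 5 CAC libraries lay above every Con and every NCAC library. In the IL-6 and STAT3 list 8 of 21 rose against Con on either scale (8 higher and 1 lower adjusted over the list alone; adjusted p = 3.43e-12, and adjusted p = 0.296 with an estimated correlation). Against NCAC 7 rose, or 8 after rescaling (10 adjusted over the list alone; adjusted p = 1.03e-13, and adjusted p = 0.226 with an estimated correlation). Of 30 nuclear respiratory chain genes 14 fell against Con, or 5 after rescaling (1 rose and 21 fell adjusted over the list alone, adjusted p = 3.78e-11, and adjusted p = 0.496 with an estimated correlation). On TPM nearly all of these 14 lost their calls without Con libraries 3 and 4, where only 1 gene of any kind was called lower. Against NCAC limma called 0 of the 30, with 0 higher and 0 lower at an unadjusted p under 0.05. The cholesterol synthesis list pointed down against NCAC with 0 of 18 genes past the limma test (1 higher and 10 lower at an unadjusted p under 0.05, 0 adjusted over the list alone; adjusted p = 2.42e-10, and adjusted p = 0.344 with an estimated correlation). The immunoglobulin gene Ighm fell by 1.93 (SE 0.40) against Con.

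In all 484 genes differed between CAC and Con at 4 weeks, 103 higher and 381 lower, and 693 after rescaling, 406 higher and 287 lower. The balance rested on Con libraries 3 and 4, whose mitochondrial share was far below the rest: without both 81 genes differed, 80 higher and 1 lower, and 100 with rescaling as well, 82 higher and 18 lower. Among the 5 largest falls were the histone genes Hist1h4h (-1.63, SE 0.30) and Hist2h2aa1 (-1.56, SE 0.29). Hist1h2al (-1.52, SE 0.37), annotated as a processed pseudogene, and Scand1 (-1.44, SE 0.35) were among them too. All of these lost their calls without these 2 libraries. Hist1h2al and Scand1 also lost them without CAC library 2 or Con library 3 or 4 alone (adjusted p = 0.0594 to 0.0984 and 0.0652 to 0.0968). The count was 65 without CAC library 2, 256 without CAC library 4, 768 without Con library 1, 948 without Con library 2, 98 without Con library 3, 92 without Con library 4 and 878 without Con library 5. Library weights gave 162 genes. When only CAC and Con libraries of 4 weeks entered the fit, 3 genes differed, and Itih4 had an adjusted p of 0.298, Hp of 0.298 and Ccl8 of 0.0571. Against NCAC 74 genes differed, all higher in CAC, and 121 after rescaling, 107 higher and 14 lower; 6 differed with only the compared groups in the fit, 126 with library weights and 44 without a filter. That count was 15 without CAC library 2, 47 without NCAC library 1, 35 without NCAC library 3 and 27 without NCAC library 4. All 74 genes were called in the same direction against NCAC at 8 weeks, where the list sizes would give 27.6, and 65 of them at 6 weeks, where they would give 4.31.

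At 2 weeks skeletal muscle transcripts were higher in CAC than in Con. Of 17 skeletal muscle genes 16 rose (15 after rescaling, 17 adjusted over the list alone; adjusted p = 1.6e-14, and adjusted p = 0.405 with an estimated correlation). The 5 largest rises were genes of slow muscle fibres and of the sarcomere: the myosin light chain Myl2 (4.23, SE 1.16; 83.6 ± 39.1 against 5.83 ± 9.09 TPM, SD, n = 5 each), the myosin heavy chain Myh7 (3.75, SE 1.05), the troponins Tnnt1 (3.63, SE 1.00) and Tnnc1 (3.6, SE 0.97), and Actn2 (3.39, SE 0.85). The mean log2 value of the muscle list was 7.63 ± 1.25 (SD, n = 5) in CAC, 6.74 ± 0.786 in NCAC and 4.78 ± 1.47 in Con (exact permutation p = 0.0159 for CAC against Con and 0.0238 for NCAC against Con, each 0.143 adjusted over 12 tests). With this mean as a covariate 2 genes differed. Markers of fibroblasts and adipocyte progenitors rose in 9 of 13 genes on either scale (13 adjusted over the list alone; adjusted p = 2.13e-13, and adjusted p = 0.226 with an estimated correlation). Macrophage markers rose in 7 of 13 on either scale (11 adjusted over the list alone; adjusted p = 2.96e-09, and adjusted p = 0.373 with an estimated correlation). Of 6 white adipocyte markers 2 rose on either scale (5 adjusted over the list alone; adjusted p = 0.00373, and adjusted p = 0.226 with an estimated correlation). The lipogenesis and triglyceride list pointed down with 0 of 20 genes past the limma test (0 higher and 2 lower at an unadjusted p under 0.05, 0 adjusted over the list alone; adjusted p = 2.16e-08, and adjusted p = 0.337 with an estimated correlation).

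Each of the 8 genes named at 2 weeks lost its call when some single libraries were left out. Myl2, Myh7, Tnnt1 and Tnnc1 lost it without CAC library 1, 2 or 4 or Con library 1, 3 or 5 (adjusted p = 0.0537 to 0.107), and Actn2 without CAC library 1 or 2 or Con library 1 (0.0696 to 0.0974). Among the falls the complement inhibitor Cd59b (-1.08, SE 0.33) lost it without any 1 of the 10 libraries except CAC library 5 (0.057 to 0.143), Id1 (-0.68, SE 0.21) without CAC library 1, 2 or 4 or Con library 1, 2, 4 or 5 (0.0774 to 0.213), and the fatty acid oxidation gene Hadhb (-0.28, SE 0.08) without CAC library 1, 2, 3 or 4 or Con library 1, 3, 4 or 5 (0.0603 to 0.106). In all 582 genes differed, 576 higher and 6 lower, and 603 after rescaling, 513 higher and 90 lower. Library weights gave 1986, only the compared groups 1207 and the filter at 5 TPM 341. The count was 58 without CAC library 1, 72 without CAC library 2, 181 without CAC library 4, 888 without CAC library 5, 91 without Con library 1, 347 without Con library 3 and 196 without Con library 5.

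Against NCAC at 2 weeks 5 genes differed by limma, all higher in CAC, and 1633 had an unadjusted p under 0.05. C4b stood at 68.4 ± 45.3 TPM (SD, n = 5) in CAC and lay between 7.28 and 22.5 TPM in the 5 NCAC libraries, a log2 change of 2.22 (SE 0.37, adjusted p = 0.0018), and the cytokine receptor subunit Csf2rb rose by 1.52 (SE 0.26, adjusted p = 0.0018). The GTPase gene Rap1a (0.34, SE 0.07) lost its call without CAC library 1, 3 or 4 or NCAC library 1, 2 or 5 (adjusted p = 0.114 to 0.199). Limma called 0 of the 17 muscle genes against NCAC (0 higher and 0 lower at an unadjusted p under 0.05, 0 adjusted over the list alone). On TPM the list did not pass (adjusted p = 0.313, and adjusted p = 0.868 with an estimated correlation). After rescaling its camera test at the preset correlation pointed up (adjusted p = 0.00775). The mean of the list did not separate CAC and NCAC (exact permutation p = 0.214). With only the compared groups in the fit limma called 0 genes, with library weights 489, without a filter 30, with the filter at 5 TPM 3, with the replicate block 3 and with quantile normalization 2. The count was 3 without CAC library 3, 9 without CAC library 5, 3 without NCAC library 1, 3 without NCAC library 2, 11 without NCAC library 4 and 2 without NCAC library 5.

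NCAC was compared with Con to ask what a non-cachectic melanoma does to brown fat. Limma called 0 genes at 2, 6 and 8 weeks, with 943, 1059 and 466 genes at an unadjusted p under 0.05, and 1 at 4 weeks, the predicted gene Gm7293, lower in NCAC, with 2206 at an unadjusted p under 0.05. Gm7293 falls outside the rule for named genes and was chosen after its value was seen. At 4 weeks the count was 0 without NCAC library 2 or 3 or Con library 3 or 4, 249 without Con library 2 and 516 without Con library 5. Library weights gave 833, 0, 226 and 9 genes at 2, 4, 6 and 8 weeks, and a fit of only the groups compared 26 at 2 weeks and 0 at the others. Quantile normalization gave 2 at 2 weeks and 0 at the others, and no filter 2 at 4 weeks and 1 at 6 weeks. The low counts therefore depend on these choices. In data simulated for NCAC against Con at 8 weeks 64.2% of genes with a true log2 change of 0.5 were recovered and 94.03% of those with a change of 1. Those changes lay only in genes above a minimum mean level, with independent noise. The shares therefore need not hold for all tested genes or for libraries whose genes vary together. At 8 weeks Itih4 was 1.42 ± 0.701 TPM in NCAC (SD, n = 5), C4b 12.8 ± 3.28 TPM and Ucp1 6263 ± 2693 TPM.

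The change of the CAC against Con difference over time was tested directly. From 2 to 8 weeks it changed for 1457 genes, 1278 upward and 179 downward, and for 861 after rescaling, 440 upward and 421 downward. Library weights gave 4999 and the replicate block 866. The difference in Itih4 grew by 6.69 (SE 0.91, adjusted p = 4.54e-06) and that in Mt2 by 4.42 (SE 0.71, adjusted p = 8.64e-05). Cyp2b10 (4.43, SE 1.41) lost its call without CAC library 1 or 5 or Con library 1 of 2 weeks, or CAC library 1 or 6 or Con library 1 or 3 of 8 weeks (adjusted p = 0.0505 to 0.0661). The muscle genes Casq1 (-4.00, SE 1.10), Ckmt2 (-3.84, SE 1.2) and Pvalb (-3.80, SE 1.15) changed most downward, beside a muscle list mean at 2 weeks of 7.63 in CAC and 4.78 in Con. Ckmt2 lost its call without CAC library 1 or 2 or Con library 1 of 2 weeks, or CAC library 5 or Con library 4 of 8 weeks (0.0518 to 0.0724), and Pvalb without library 1 of CAC or Con at 2 weeks or Con library 4 at 8 weeks (0.0606 to 0.0681). The count was 880 without CAC library 1 of 2 weeks, 923 without CAC library 2 of 2 weeks, 957 without CAC library 2 of 8 weeks, 2825 without CAC library 3 of 8 weeks and 857 without Con library 1 of 8 weeks.

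From 2 to 6 weeks the difference changed for 167 genes, 124 upward and 43 downward, and for 327 after rescaling, 159 upward and 168 downward. Library weights gave 1470 and only the compared groups 531. That count was 82 without CAC library 1 and 90 without CAC library 2 of 2 weeks, 100 without Con library 1 of 2 weeks, 72 without CAC library 1 of 6 weeks and 98 without Con library 5 of 6 weeks. From 6 to 8 weeks it changed for 1 gene, the predicted Gm7334 (1.66, SE 0.32, adjusted p = 0.036), with 1002 genes at an unadjusted p under 0.05. For this change library weights gave 446 genes, and 0 were called by limma without a filter, after median-of-ratios rescaling or quantile normalization, with only the compared groups or with the replicate block. Within Con, 4 genes differed between 8 and 2 weeks, all lower at 8 weeks: the endothelial receptor Tie1 (-0.71, SE 0.14), Cisd3 (-0.54, SE 0.11), Pik3r6 (-0.48, SE 0.10) and Dhodh (-0.39, SE 0.08), with 2553 at an unadjusted p under 0.05. The count of 4 varied widely with the processing: 4066 with library weights (482 higher, 3584 lower), 1299 with only the compared groups (113 higher, 1186 lower), 56 with the filter at 5 TPM, 29 with a pseudocount of 0.1, 9 with the replicate block, and 0 by limma without a filter or with quantile normalization. After median-of-ratios rescaling 27 were called, 22 of them higher, so the balance turned. These 5 genes were chosen after their values were seen. The count from 6 to 8 weeks was 0 without CAC library 3 or 4 or Con library 2, 3 or 4 of 6 weeks, 0 without CAC library 1, 4, 6 or 7 or Con library 3, 4 or 5 of 8 weeks, 11 without CAC library 3 and 2 without CAC library 5 of 8 weeks. The count within Con was 0 without library 1, 2, 3 or 4 of 2 weeks or library 1, 3 or 4 of 8 weeks, 15 without library 5 of 2 weeks and 207 without library 2 of 8 weeks.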

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

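The counts over other splits of the libraries were chosen after the results were seen. So were the tests of the shifted balance of calls at 8 weeks and of the muscle transcripts at 2 weeks. The tests of the epithelial transcripts were written down before they were run, but for a fall that the pattern itself names.

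The first pattern is the excess of higher calls in CAC against Con at 8 weeks, 6549 of 6797 genes. TPM has a fixed total, and CAC had less of it in mitochondrially encoded transcripts. With these genes removed and the rest rescaled, 38.2% of the called genes were higher, but rescaling to a fixed total also moved the median over all genes from 0.28 to -0.05, which by itself sets this balance. A lower share under a fixed total and a rise of most other transcripts per cell, by the median log2 difference of 0.28, cannot be told apart without a spike-in. The share was also lower in CAC than in NCAC (exact permutation p = 0.00253), a value seen before this explanation was written. Both of these arms had received melanoma cells, so that test does not set a tumour against none. NCAC against Con gave an exact permutation p = 0.0714 (adjusted p = 0.143). An effect of the cachectic tumour on the share therefore stays open.

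The second pattern is the rise of skeletal muscle transcripts in CAC against Con at 2 weeks. With the mean of the fixed muscle list as a covariate 2 of the 582 called genes were still called, C4b and Gm20721, and the median log2 change of the 582 went from 0.95 (median SE 0.25) to 0.28 (median SE 0.18), so the calls ended because the differences shrank. Muscle carried over with the dissected tissue is a candidate explanation, and so is anything else that moves with these transcripts. A response to the cachectic tumour cannot be told apart from it: the list mean was higher by 0.89 in CAC than in NCAC (exact permutation p = 0.214), with 5 libraries each. At 2 weeks Acta1, an abundant muscle transcript, had 2252 ± 1737 TPM (SD, n = 5) in CAC and 299.6 ± 303 TPM in Con.

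The third pattern is the lower level of epithelial transcripts in CAC at 8 weeks. Over the 40 NCAC and Con libraries, as deviations from group means, the 13 genes of the list had a median pairwise Pearson's r of 0.82 and Spearman's rho of 0.81 (permutation p = 0.001 for each, the smallest that 1000 permutations can give). Without the 2 libraries farthest from the median r was 0.79, and random lists gave 0.132 to 0.439. A varying amount of epithelium in the dissected tissue is therefore a candidate explanation. A response to the cachectic tumour also stays open. The list mean was lower by 1.19 in CAC than in NCAC (exact permutation p = 0.00758) and by 1.00 than in Con (p = 0.0126). Each was 0.0504 adjusted over 8 tests. These tests use the same genes and libraries as the fall itself, so they add no separate support. Krt8 and Krt18 averaged 15.1 ± 9.09 and 17.8 ± 12.1 TPM (SD, n = 5) in Con at 8 weeks.

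Single libraries stood far from the rest of their group in 12 of 123 sets of values, where chance gives about 1 in 20 if values are normally distributed. TPM values need not be, and the sets share libraries, so no excess over chance is shown. Among library measures, NCAC library 2 of 2 weeks had a mitochondrial share of 61.7%, and the number of genes at 1 TPM or more was 11269 in Con library 2 of 2 weeks and 11030 in NCAC library 3 of 4 weeks. At 8 weeks Ccl8 was 249 TPM in CAC library 2, and CAC library 3 had 41.9 TPM of Itih4 and 6.1 TPM of Fndc5. NCAC library 3 of 8 weeks had 11.5 TPM of Cxcl13, 96.5 TPM of Cyp2b10 and 2.62 TPM of Itih4. Krt18 was 13.8 TPM in CAC library 6, Mmd2 57.9 TPM in NCAC library 4 and Serpina3k 1.49 TPM in Con library 2, all at 8 weeks.

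The CAC against Con difference changed with time for 167 genes from 2 to 6 weeks, 1457 from 2 to 8 weeks and 1 from 6 to 8 weeks. Of 32 named genes looked at from 2 to 8 weeks 16 passed, where 1457 of all 12581 tested genes did. That share is not a test, because the naming rule took Itih4, Cyp2b10, Mt2, Casq1, Ckmt2 and Pvalb from genes that passed here. The others were named for an extreme change against Con at 8 weeks or were fixed in advance. The change was 6.69 for Itih4, 4.43 for Cyp2b10, 4.42 for Mt2, 4.34 for Serpina3k, 4.09 for Cxcl13, 3.97 for Hp, 3.68 for Fkbp5, 3.59 for Serpina3n, 2.59 for C4b, 2.27 for Ccl8 and 0.90 for Pnpla2. It was -1.43 for Apln, -2.59 for Fndc5, -3.80 for Pvalb, -3.84 for Ckmt2 and -4.00 for Casq1, the last 3 being muscle genes.

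Each count was set against 100 splits of the same libraries, the real split included. Only the real split reached 582 genes for CAC against Con at 2 weeks (highest other 291), 2731 at 6 weeks (945) and 6797 at 8 weeks (4851). Against NCAC only the real split reached 74 at 4 weeks (49), 977 at 6 weeks (210) and 4947 at 8 weeks (4655). The same held for 167 genes from 2 to 6 weeks (27), 1457 from 2 to 8 weeks (1137), 4 within Con (3) and 4608 against both groups (2208). The 5 genes of CAC against NCAC at 2 weeks were reached by 2 splits, the highest other giving 5. For each of these 11 counts the share of splits that reached it was under 0.05, without adjustment over the counts. For the changes over time the splits mixed CAC and Con within each week. They therefore address any difference between the 2 arms and not its change. Splits that mix groups that differ also widen the spread within groups, which lowers their counts. The highest other split came close to the real count for the 5 genes, for the 4947 and, less so, for the 1457 and the 4. The 5 became 0 by limma with only the compared groups in the fit, and the 4 became 0 without any 1 of 7 of the 10 libraries, so these 2 counts are weak. Chance cannot be excluded for CAC against Con at 4 weeks, where 11 splits reached 484 and the highest other gave 1508, or for NCAC against Con at 4 weeks, where 10 splits reached 1 and the highest gave 1567. Nor can it for the change from 6 to 8 weeks, where 13 splits reached 1 and the highest gave 6211. Splits that call several times the real count point to a structure of the samples, at 4 weeks with Con libraries 3 and 4 standing apart. For NCAC against Con at 2, 6 and 8 weeks the real count was 0, which all 100 splits reach, and the highest others were 0, 36 and 0.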

How the results depend on the processing

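Every alternative that removes mitochondrially encoded genes, uses the muscle covariate or leaves out Con libraries 3 and 4 of 4 weeks was chosen after the data were seen. Counts not named for a setting stayed within 1.5 times the reported count. Where only the filter or the groups in the fit changed, fewer or more genes or libraries entered. For the other moved counts and reversals the cause was not tested, except where a scale is named.

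With a pseudocount of 0.1, Con at 8 against 2 weeks gave 29 genes. Without a filter CAC against NCAC gave 30 at 2 weeks and 44 at 4 weeks. NCAC against Con gave 2 at 4 weeks and 1 at 6 weeks, and the change from 6 to 8 weeks and Con over time 0 each. With the filter at 5 TPM CAC against Con at 2 weeks gave 341, CAC against NCAC at 2 weeks 3 and Con over time 56. The cell cycle list for CAC against NCAC at 8 weeks had a median of 0.18 relative to all genes, and its test no longer pointed down.

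With median-of-ratios rescaling CAC against NCAC at 4 weeks gave 121, CAC against Con 1050 at 6 weeks and 3333 at 8 weeks, and CAC against NCAC at 8 weeks 3105. The changes from 2 to 6, 2 to 8 and 6 to 8 weeks gave 327, 861 and 0, Con over time 27 and both groups at 8 weeks 2342. Quantile normalization gave 2 for CAC against NCAC and 2 for NCAC against Con at 2 weeks, and 0 for NCAC against Con at 4 weeks. It gave 1065 and 3496 for CAC against Con at 6 and 8 weeks and 3154 for CAC against NCAC at 8 weeks. It also gave 327 and 0 for the changes from 2 to 6 and 6 to 8 weeks, 0 for Con over time and 2423 for both groups.

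With only the groups compared, CAC against Con gave 1207 at 2 weeks and 3 at 4 weeks, and CAC against NCAC 0, 6 and 2736 at 2, 4 and 8 weeks. NCAC against Con gave 26 and 0 at 2 and 4 weeks, the changes from 2 to 6 and 6 to 8 weeks 531 and 0, and Con over time 1299. Library weights gave 1986 and 162 for CAC against Con at 2 and 4 weeks, and 489, 126 and 2442 for CAC against NCAC at 2, 4 and 6 weeks. They gave 833, 0, 226 and 9 for NCAC against Con at 2, 4, 6 and 8 weeks. They gave 1470, 4999 and 446 for the changes from 2 to 6, 2 to 8 and 6 to 8 weeks, and 4066 for Con over time.

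The replicate numbers do not pair the libraries, since libraries of the same number were most alike in 12 of 60 cases. As a block they gave 3 for CAC against NCAC at 2 weeks, 866 and 0 for the changes from 2 to 8 and 6 to 8 weeks, 9 for Con over time and 5811 for CAC against Con at 8 weeks.

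Without mitochondrially encoded genes CAC against Con gave 772, 1313 and 3430 at 4, 6 and 8 weeks, and CAC against NCAC 132, 1563 and 3095. NCAC against Con at 4 weeks gave 2, the change from 2 to 6 weeks 522, Con over time 17 and both groups 2415. The muscle covariate gave 2 for CAC against Con at 2 weeks, 61 for the change from 2 to 6 weeks and 0 for Con over time. The covariate with median-of-ratios rescaling gave 6, 906, 1172 and 3643 for CAC against Con at 2, 4, 6 and 8 weeks, 148 and 1557 for CAC against NCAC at 4 and 6 weeks, and 0 for NCAC against Con at 4 weeks. Both together gave 73, 462 and 0 for the changes from 2 to 6, 2 to 8 and 6 to 8 weeks, 0 for Con over time and 2611 for both groups. Without Con libraries 3 and 4 of 4 weeks, CAC against Con gave 81 and NCAC against Con 0.

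For CAC against Con at 8 weeks some small rises turned sign once the all-gene shift was removed. List values in this paragraph are medians relative to all genes, given where the direction of the list test turned. With median-of-ratios rescaling Etfb was -0.12, Atp5c1 -0.01, Sdha -0.03, Cox7b -0.09 and Atp5b -0.12. With quantile normalization Cidea was 0, Etfb -0.01, Atp5c1 -0.02 and Atp5b -0.19, while mt-Cytb, a fall on TPM, was 0.12. The median of the mitochondrial genome list was 0.06 against Con and 0.01 against NCAC at 2 weeks. Without mitochondrially encoded genes Etfb was -0.16, Atp5c1 -0.05, Sdha -0.07, Cox7b -0.13, Atp5b -0.16 and Idh3g -0.03. The muscle list median relative to all genes was then 0.03 at 6 weeks and 0.15 at 8 weeks. On TPM it was 0.06 and 0.17, so the direction of its test turned while the sign of the median did not. With rescaling and the covariate Etfb was -0.13, Atp5c1 -0.01, Sdha -0.03, Cox7b -0.09 and Atp5b -0.13. The muscle list was then -0.02, 0.09 and 0.26 against Con at 2, 6 and 8 weeks and 0.18 against NCAC at 8 weeks. With the covariate alone that list was -0.08 against Con and -0.06 against NCAC at 2 weeks. The covariate is the mean of the same muscle genes, so the fit itself takes the mean difference of that list out. The turns of the muscle list under the covariate, with or without rescaling, therefore say nothing about the list. For CAC against Con at 4 weeks the mitochondrial genome list was -0.03 with library weights and -0.16 without Con libraries 3 and 4.

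Leaving out 1 library gave 58 to 888, 65 to 948, 1593 to 3203 and 5596 to 7323 genes for CAC against Con at 2, 4, 6 and 8 weeks. It gave 2 to 11, 15 to 107, 593 to 1072 and 3759 to 5854 for CAC against NCAC, and 0 to 0, 0 to 516, 0 to 0 and 0 to 0 for NCAC against Con. The ranges were 72 to 236, 857 to 2825 and 0 to 11 for the changes from 2 to 6, 2 to 8 and 6 to 8 weeks, 0 to 207 for Con over time and 3576 to 5510 for both groups.

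Among named genes, 30 calls were lost and 7 gained with median-of-ratios rescaling and 25 lost and 2 gained with only the groups compared, while a pseudocount of 0.1 lost 1 and gained 2. Among list tests, 29 were lost and 21 gained with median-of-ratios rescaling and 50 lost and 17 gained with quantile normalization. TPM gives no depth, so what depth limits cannot be shown. In data simulated for CAC against Con 68.7% of true log2 changes of 0.5 were recovered at 8 weeks and 58.2% at 4 weeks. Those changes too lay only in genes above a minimum mean level.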

Other observations

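The gene groups here were chosen after the values were seen. More complement genes were called in CAC at later weeks: against Con 4 of 12 tested genes were higher at 4 weeks, 10 at 6 weeks and 12 at 8 weeks, with 0 lower, and 7, 9 and 10 after rescaling. Over all 12581 tested genes 103, 2608 and 6549 were higher at these weeks, or 406, 652 and 1680 after rescaling. CAC also had 7 libraries at 8 weeks and 5 at the earlier weeks. The counts alone therefore do not show a growth particular to this group. The change over time was not tested for the group. The test of the change from 6 to 8 weeks called 1 gene, Gm7334, which is not among these 12 complement genes. At 8 weeks C3, the central complement protein, had 1223 ± 417 TPM (SD, n = 7) in CAC and 440 ± 86.3 TPM (n = 5) in Con (log2 change 1.39, SE 0.22), Cfb rose by 2.27 (SE 0.26), C6 by 2.24 (SE 0.20) and the inhibitor Serping1 by 1.65 (SE 0.21). Against NCAC at 8 weeks all 12 were higher on either scale. Of 5 tested Serpina3 genes, whose reads are hard to tell apart, 1 was higher at 4 weeks and 5 at 6 and 8 weeks against Con, or 2, 4 and 5 after rescaling.

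Of 10 tested imprinted genes, many of which control growth, 2 rose at 8 weeks against Con on either scale, Peg3 (1.23) and Grb10 (0.75), and 5 fell: Cdkn1c (-1.41), Ndn (-1.19), Gpc3 (-0.64), Dlk1 (-0.44) and Igf2 (-0.39). Of 6 tested genes of antigen presentation by MHC class II limma called 0 at 4 and 8 weeks against Con and 0 at 8 weeks against NCAC, with 0 at an unadjusted p under 0.05. At 6 weeks 1 was lower against Con, or 3 after rescaling. The call on TPM was H2-Aa, lost without CAC library 1 or Con library 5 (adjusted p = 0.0727 to 0.124).

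Transcripts of T cells were near 0 in the 62 libraries: the median was 0.0295 TPM for Cd3e and 0 TPM for Cd8a, and the highest value of Trac was 1.44 TPM. These values do not settle whether the mice were nude or C57BL/6J. Of the melanocyte and melanoma list 3 genes could be tested. Against Con at 8 weeks 1 rose, Mitf (0.43), a call that ended without CAC library 1, 2 or 6 or Con library 1, 2 or 5 (adjusted p = 0.0631 to 0.121) and that was not made after rescaling. The list had an adjusted p = 0.15, an adjusted p = 0.504 with an estimated correlation, and 1 gene higher adjusted over the list alone.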
